A study of Homo sapiens with 23 samples.

How the data were processed

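The series holds RNA sequencing of MB468 cells, the usual short name of MDA-MB-468, an established human cell line that the labels describe as a triple-negative breast cancer line (without the estrogen and progesterone receptors and HER2). There are 2 datasets. The knockdown dataset has 5 control libraries, 5 libraries with knockdown of PRPF8 and 5 with knockdown of PRPF38A. The E7107 dataset has 4 control libraries and 4 libraries treated with E7107, an inhibitor of the SF3b complex of the U2 snRNP. Per the labels' protocols, 100000 cells per well were reverse-transfected with 50 nM siRNA and adherent cells were collected 48 h after transfection, RNA was purified with a column kit, and libraries were made with a stranded mRNA kit. That protocol names a non-targeting siRNA, while the titles call the controls untreated, and the same protocol text stands on the E7107 samples, whose dose and time are not given in the sources used here. The groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

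Per the submitters' processing notes, STAR 2.4.1d, DESeq2 1.12.3, sleuth 0.28 and the genome build GRCh37 were used, with no role or order given. The transcript quantifier and the annotation release are not given in the sources used here. The authors deposited estimated counts per gene as whole numbers. In genes with over 300 counts in every library, the ratio of count to TPM kept to 1 factor per gene and 1 per library within 0.187% in the knockdown dataset and within 0.181% in the E7107 dataset, so the counts behave as gene TPM scaled with 1 length per gene. They were therefore handled as estimated (expected) counts and, being whole already, needed no rounding. The authors also deposited TPM (transcript abundance scaled to a fixed total) per gene and per transcript, which sum to a fixed total per library. The deposited splicing table gives percent spliced in (PSI) as a fraction from 0 to 1 per event with its informative reads, for the 15 knockdown libraries, and per the file headers it holds posterior means from MISO for events of the classes retained intron, skipped exon, alternative 3' and 5' splice site and mutually exclusive exons. Event positions are those of the deposited table, and GRCh37 is the only build the processing notes name; the events carry no gene names and none were added. The authors' deposited gene tables give a log2 fold change and an adjusted p-value, and their deposited transcript tables give an effect on the natural log scale, a q-value, gene names and transcript biotypes. A second count table for the knockdown transcripts was not used, nor was the E7107 table named as transcript counts, whose content is identical to the gene count table. No column of values per library was left without a sample.

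Total counts per library were 44380772 to 79147881 in the knockdown dataset and 40163238 to 73317291 in the E7107 dataset. No pair of libraries agreed within sampling noise: within groups, chi-square over its degrees of freedom was 5.87 to 129. Control replicates 1 to 3 differed less from each other (5.87 to 9.07) than from control replicates 4 and 5 (26.93 to 42.22). The cause of this was not tested. Symbols came from the authors' tables for 38148 of 57905 genes of the knockdown count table, with 10351 more from the reference name table, and for 35660 of 37554 genes of the E7107 count table.

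Gene counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the robust quasi-likelihood test, each dataset in its own fit with a term per group, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and calls with a log2 change of at least 1 were also counted. The biological coefficient of variation was 0.103 in the knockdown dataset and 0.175 in the E7107 dataset. Levels are TMM-scaled CPM (counts scaled to library size). Differences between the E7107 change and a knockdown change were tested as a contrast over all 23 libraries, for genes in both tables. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32 lists of a comparison, and again with a correlation estimated from the data and with fry, which asks if a set's genes move on balance in 1 direction and does not compare the set with other genes. Splicing events were tested with limma on logit PSI held between 0.01 and 0.99, for events with at least 20 informative reads in every library of the comparison, and called at an adjusted p under 0.05 and a PSI difference of at least 0.1. The share of TPM in each transcript biotype was compared with two-sided exact permutation tests, whose smallest p is 0.0079 for 5 against 5 libraries and 0.0286 for 4 against 4. Biotypes came from the authors' transcript tables, for 76186 of 196501 transcripts with at least 91.5% of each knockdown library's TPM and at least 89.9% of each E7107 library's. The share of each gene's TPM in retained-intron transcripts was tested with limma on the logit scale and called at an adjusted p under 0.05 and a difference of at least 10 percentage points, for genes with a mean TPM of at least 5 and a TPM above 0 in every library of the dataset. This test and the classes by intron number were added after seeing the data. Intron numbers and the positions of PRPF8 transcripts came from GENCODE release 29 on GRCh38.

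Scripts were tested on simulated data with 100 changed genes or events per size. For the PRPF8 comparison, 97% of 2-fold and 80% of 1.5-fold changes were called over 18944 genes, and 0.04% of unchanged genes. For the E7107 comparison the shares were 85%, 61% and 0.04% over 17234 genes. In both gene simulations few genes changed and as many rose as fell. Errors of scaling and data in which most genes change were therefore not covered. For PRPF8 splicing events, 63% of PSI differences of 0.2 and 13% of those of 0.1 were called over 32024 events (26% of the latter passed the adjusted p, and the PSI minimum equals that difference), and no unchanged event was called. For retained-intron shares with PRPF8 knockdown, 83% of differences of 0.2 and 38% of those of 0.1 were called over 4570 genes, and with E7107 53% and 22% over 4484.

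The designs, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes PRPF8 and PRPF38A, with SF3B1 and PHF5A for E7107. It takes up to 8 genes with the largest increase and 8 with the largest decrease per comparison, and 5 of each for the contrast of the knockdowns, among called genes with a mean CPM of at least 10 in the higher group and no overlap of libraries between groups. It takes up to 4 members per list, the 6 genes most raised and the 6 most lowered in all 3 comparisons, and up to 5 events per type. The text names a part of these. The lists were U5 and tri-snRNP, B-complex, U2 snRNP and SF3, Prp19-complex, exon junction complex, SR and hnRNP, minor spliceosome and nonsense-mediated decay proteins; transcripts known to be degraded by nonsense-mediated decay; mitosis, cohesion, replication, recombination repair and histone genes; anti-apoptotic, pro-apoptotic, p53 target, integrated stress response, immediate early, heat shock, NF-kB and interferon genes; proteasome, ribosomal protein, oxidative phosphorylation, mitochondrially encoded, cholesterol and glycolysis or hypoxia genes; and basal, luminal, mesenchymal and immune or endothelial cell markers. Alternatives were DESeq2's size factors in edgeR, upper quartile scaling, no filter on low counts, a mean CPM of at least 5, the DESeq2 1.42.0 Wald test, the replicate number as a block, only the compared groups, limma on log2(TPM + 1) and log2(TPM + 0.1), other PSI and read minimums, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps. Intervals between builds were not converted. The genes of closely related families, such as the UGT1A genes, actins, histones and ribosomal proteins with their pseudogenes, share sequence, and reads split between their copies make these values uncertain. How fully the mRNA kit captured histone mRNAs was not tested, so histone changes are those of the captured RNA.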

Results

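Gene expression and splicing were measured by RNA sequencing in MDA-MB-468 breast cancer cells after knockdown of PRPF8 or PRPF38A (5 libraries each, with 5 controls) and, in a separate dataset, after treatment with E7107 (4 libraries, with 4 controls). PRPF8 is the central protein of the U5 snRNP and of the active spliceosome, PRPF38A is a protein of the spliceosomal B complex, and E7107 inhibits the SF3b complex. The series title puts the question as the reliance of these cells on RNA splicing. The comparisons were each knockdown and E7107 against their own controls, the knockdowns against each other, and the E7107 changes against the knockdown changes. Total counts per library ran from 44380772 to 79147881 in the knockdown dataset and from 40163238 to 73317291 in the E7107 dataset. Mitochondrially encoded genes held 1.79% to 2.57% of counts in the controls, 2.74% to 4.41% with PRPF8 knockdown, 2.23% to 2.94% with PRPF38A knockdown, 2.12% to 2.3% in the E7107 controls and 4.16% to 5.94% with E7107. The most abundant gene (ENSG00000266658) has no symbol in the files, and whether it derives from ribosomal RNA or a repeat was not tested. It held 1.61% to 1.75% of counts in the controls, 1.76% to 4.1% with PRPF8 knockdown, 2.05% to 3.32% with PRPF38A knockdown, 1.36% to 1.63% in the E7107 controls and 5.05% to 6.98% with E7107.

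Each targeted gene was low in all 5 libraries of its own knockdown. PRPF8 (ENSG00000174231) stood at 22.8 ± 3.3 CPM with PRPF8 knockdown (SD, n = 5, range 19.7 to 26.5) against 293.7 ± 62.58 CPM in the controls (SD, n = 5), a log2 change of -3.69 ± 0.14 (SE). PRPF38A (ENSG00000134748) stood at 7.1 ± 0.71 CPM with PRPF38A knockdown (SD, n = 5, range 6.5 to 8.1) against 171.4 ± 6.21 CPM in the controls, a log2 change of -4.60 ± 0.06 (SE). The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 4.17e-12 for PRPF8 and 1.45e-20 for PRPF38A. Control replicate 5 had 405.4 CPM of PRPF8, while the other 4 controls had 258.9 to 268.6. PRPF8 stood at 362.9 to 419.2 CPM with PRPF38A knockdown (log2 change 0.40, adjusted p = 0.0121 in edgeR's quasi-likelihood test). PRPF38A stood at 200 to 214 CPM with PRPF8 knockdown, a log2 change of 0.29. On the log2(TPM + 0.1) scale, where the median of all genes was -0.21, the change was 0.06 (adjusted p = 0.376 in limma). In the E7107 dataset PRPF8 lay at 480.6 to 500.5 CPM in the controls and 420.0 to 492.4 with E7107, and PRPF38A at 124.3 to 130.2 and 28.1 to 36.4.

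**Figure D1:**
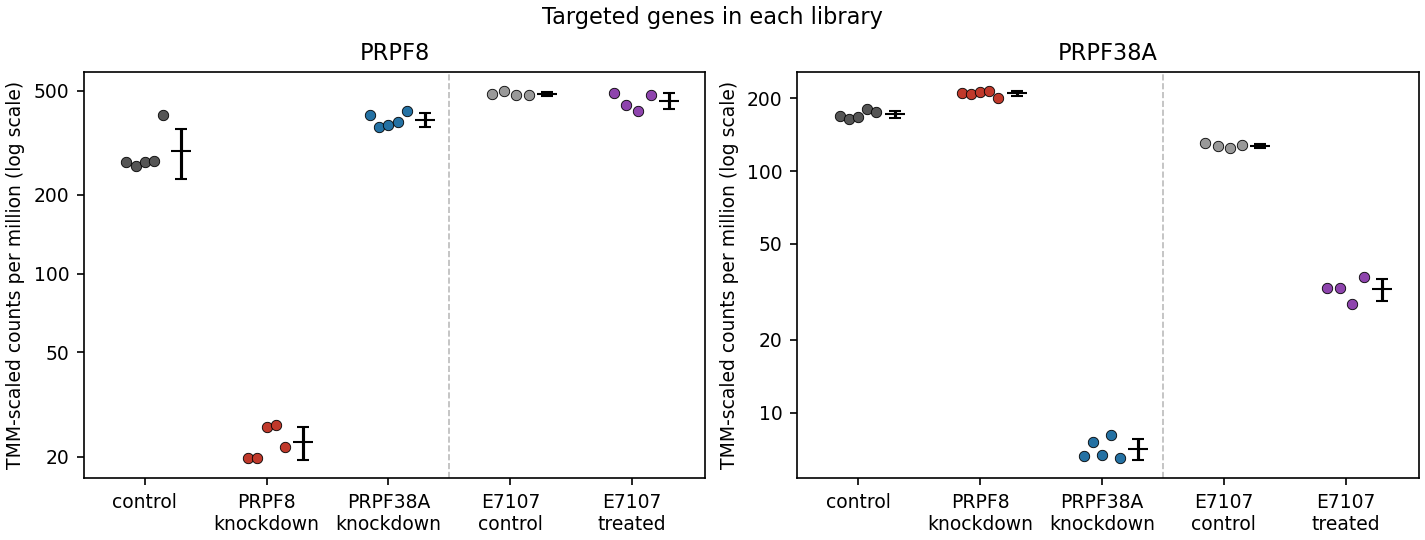
TMM-scaled CPM of PRPF8 and PRPF38A on log axes, with a point per library and a bar for the mean ± SD of each group (n = 5 per group in the knockdown dataset, n = 4 in the E7107 dataset, right of the dashed line). PRPF8 lies at 19.7 to 26.5 in its knockdown and 258.9 to 405.4 in the controls, and PRPF38A at 6.5 to 8.1 in its knockdown and 164.8 to 179.8 in the controls.

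PRPF8 knockdown raised CTGF, a secreted matrix-associated growth factor, from 6.57 ± 2.01 to 338.2 ± 29.5 CPM (SD, n = 5 each; log2 change 5.68 ± 0.17, SE). The smooth muscle actin ACTG2 (5.24 ± 0.13), the muscle ankyrin repeat gene ANKRD1 (5.21 ± 0.16), the insulin-like growth factor binding protein IGFBP5 (4.44 ± 0.07), the chemokine CXCL8 (4.29 ± 0.13) and the myosin light chain MYL9 (3.71 ± 0.12) rose as well, although ACTG2 shares sequence with the other actins. The corepressor RCOR2 (-4.46 ± 0.09), the chloride channel regulator CLCA2 (-4.41 ± 0.35), the phospholipase PLCB3 (-3.92 ± 0.12) and the mitochondrial carrier SFXN2 (-3.75 ± 0.20) fell. The adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 4e-08, that of CLCA2. In all, 13910 of 19758 genes were called, 6886 higher and 7024 lower, of which 2015 and 2722 changed at least 2-fold. On the log2(TPM + 0.1) scale the median of all genes was -0.21, and the calls split into 4811 higher and 9167 lower.

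Among the fixed lists, the largest rises after PRPF8 knockdown were those of the NF-kB genes and of transcripts known to be degraded by nonsense-mediated decay. Of 18 NF-kB and inflammatory genes, 17 rose and 1 fell (median log2 change 1.35, camera adjusted p = 0.000103, and adjusted p = 0.348 with an estimated correlation). ICAM1 stood at 3.03, CXCL8 at 4.29 and the inhibitor TNFAIP3 at 1.93. Of 16 transcripts known to be degraded by nonsense-mediated decay, 14 rose, 1 fell and 1 was not called (median 1.09, camera adjusted p = 2.22e-06, and adjusted p = 0.348 with an estimated correlation). The snoRNA host SNHG1 stood at 2.59, GADD45A at 2.07 and ZFAS1 at 1.15. Of the spliceosome lists, 4 rose too. Of 18 U2 snRNP and SF3 genes 16 rose and none fell (median 0.36, camera adjusted p = 0.00047, and adjusted p = 0.348 with an estimated correlation). The helicase DDX46 stood at 0.92 and SF3B1 at 0.57. Of 21 Prp19-complex genes 17 rose and 2 fell (median 0.38, camera adjusted p = 0.00169, and adjusted p = 0.408 with an estimated correlation). RBM22 stood at 0.72 and PLRG1 at -1.10. Of 16 U5 and tri-snRNP genes 13 rose and 2 fell, PRPF8 itself among them (median 0.26, camera adjusted p = 0.0157, and adjusted p = 0.581 with an estimated correlation). PRPF3 stood at 1.91 and PRPF31 at -1.14. Of 11 B-complex genes 9 rose and 2 fell (median 0.30, camera adjusted p = 0.0197, and adjusted p = 0.395 with an estimated correlation). The kinase PRPF4B stood at 1.23 and WBP4 at -1.45.

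Ribosomal protein genes and mitochondrially encoded mRNAs rose with PRPF8 knockdown, while replication and mitosis genes fell. Of 61 cytosolic ribosomal protein genes, 53 rose and 3 fell (median 0.28, or 0.06 on the TPM scale where the median of all genes was -0.21; camera adjusted p = 1.7e-07, and adjusted p = 0.581 with an estimated correlation). RPL5 stood at 0.83 and RPS25 at 0.68. All 13 mitochondrially encoded mRNAs rose (median 0.58, camera adjusted p = 0.0297, and adjusted p = 0.766 with an estimated correlation), MT-ND1 by 0.81, and replicate 3 held the highest mitochondrial share of its group, 4.41% against 2.74% to 3.14%. Of 23 targets of the transcription factor ATF4 and the integrated stress response, 14 rose and 4 fell (median 0.44, camera adjusted p = 0.0354, and adjusted p = 0.441 with an estimated correlation). PPP1R15A, a phosphatase subunit of this response, stood at 1.40. Of 34 DNA replication genes 23 fell and 7 rose (median -0.31, camera adjusted p = 0.0042, and adjusted p = 0.348 with an estimated correlation). The polymerase POLD1 stood at -1.89 and the helicase MCM7 at -1.51. Of 35 mitosis genes 23 fell and 6 rose (median -0.20, camera adjusted p = 0.00803, and adjusted p = 0.604 with an estimated correlation). CDC20 stood at -1.26 and PLK1 at -0.83. Of 26 interferon-stimulated genes 17 fell and 4 rose (median -0.61, camera adjusted p = 0.0157, and adjusted p = 0.408 with an estimated correlation). MX1 stood at -1.10 and USP18 at -1.06. Relative to the median of all genes on the TPM scale, the list medians were 1.14 for NF-kB genes, 1.08 for transcripts degraded by nonsense-mediated decay, 0.35 for U2 snRNP, 0.36 for Prp19-complex, 0.25 for U5 and 0.28 for B-complex genes, 0.27 for ribosomal proteins, 0.56 for mitochondrially encoded mRNAs, 0.43 for stress response targets, -0.33 for replication, -0.22 for mitosis and -0.59 for interferon genes.

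The other 20 lists did not pass camera after PRPF8 knockdown, and their members went both ways. Counts of members higher and lower were 5 and 1 of 8 exon junction complex genes (camera adjusted p = 0.116), 16 and 7 of 30 SR and hnRNP genes (0.298), 3 and 4 of 8 minor spliceosome genes (0.705). They were 3 and 6 of 10 decay factors (0.569), 9 and 5 of 15 cohesion genes (0.266), 7 and 11 of 22 recombination repair genes (0.569) and 2 and 4 of 14 histone genes (0.782). They were 4 and 3 of 9 anti-apoptotic genes (camera adjusted p = 0.806), 9 and 7 of 20 pro-apoptotic genes (0.614), 10 and 8 of 20 p53 targets (0.756). Counts were 12 and 6 of 23 immediate early genes (0.173), 7 and 4 of 13 heat shock genes (0.947), 11 and 11 of 30 proteasome genes (0.709) and 13 and 16 of 33 oxidative phosphorylation genes (0.569). They were 7 and 13 of 22 cholesterol synthesis genes (camera adjusted p = 0.116), 13 and 9 of 25 glycolysis and hypoxia genes (0.569), 11 and 4 of 18 basal epithelial markers (0.07). Among cell markers they were 5 and 7 of 15 luminal markers (0.569), 5 and 2 of 10 mesenchymal markers (0.569) and 4 and 3 of 9 immune or endothelial markers (0.709). The median, the mean and the camera direction differed in sign for the histone, p53 target and heat shock lists. Adjusted over the list alone, the counts were the same except for the U2 snRNP genes (16 higher, 1 lower), the heat shock genes (7 and 5) and the ribosomal protein genes (54 and 3).

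At a mean CPM of at least 5, the camera adjusted p rose to 0.0738 for the U5 list, 0.0793 for the B-complex list, 0.124 for the stress response list, 0.0738 for the interferon list and 0.0906 for the mitochondrially encoded list. Without control replicate 4 or control replicate 5 it was 0.0556 and 0.0515 for the stress response list and 0.0542 and 0.0506 for the mitochondrially encoded list, and it was 0.0557 for the stress response list with only the compared groups in the fit. The basal marker list passed, higher, without control replicate 3 (0.0487). In the authors' deposited table, 14479 genes had an adjusted p under 0.05, 6667 higher and 7812 lower, and the 13113 genes called there and in the edgeR fit had the same sign in both.

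PRPF38A knockdown changed fewer genes and by less. The glucuronosyltransferase gene UGT1A6 (3.47 ± 0.20, SE), which shares exons with the other UGT1A genes, KIAA0040 (2.90 ± 0.05), CTGF (2.88 ± 0.16), the secreted protein gene C1QTNF6 (2.56 ± 0.06) and the vesicle transport GTPase SAR1B (2.55 ± 0.07) rose on the log2 scale. CTGF went from 6.57 ± 2.01 to 48.67 ± 4.07 CPM (SD, n = 5 each). CLCA2 (-2.94 ± 0.31), the cyclin-dependent kinase inhibitor CDKN2D (-2.20 ± 0.05) and SFXN2 (-2.12 ± 0.17) fell. The adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 1.59e-06, that of CLCA2. In all, 10993 of 19758 genes were called, 5338 higher and 5655 lower, with 969 and 895 at least 2-fold.

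Inflammatory, immediate early and histone genes rose after PRPF38A knockdown. Of 18 NF-kB genes 15 rose and none fell (median log2 change 1.10, camera adjusted p = 4.19e-06, and adjusted p = 0.391 with an estimated correlation). CXCL8 stood at 3.12 and TNFAIP2 at 1.04. Of 23 immediate early genes 17 rose and 1 fell (median 0.32, camera adjusted p = 0.00041, and adjusted p = 0.583 with an estimated correlation). MYC stood at 1.16 and JUN at 1.01. Of 14 histone genes 8 rose and none fell (median 0.58, camera adjusted p = 0.00631, and adjusted p = 0.583 with an estimated correlation). HIST1H2AC stood at 1.30 and HIST1H2BK at 1.10. These are changes of histone RNA as captured by the mRNA kit. Of 16 transcripts degraded by nonsense-mediated decay 10 rose and 2 fell (median 0.26, camera adjusted p = 0.0167, and adjusted p = 0.583 with an estimated correlation). SNHG1 stood at 0.84 and SNHG8 at 0.65. Of 16 U5 and tri-snRNP genes 11 rose and 3 fell (median 0.16, camera adjusted p = 0.0351, and adjusted p = 0.583 with an estimated correlation). PRPF3 stood at 1.46 and PRPF4 at 0.83. Ribosomal protein genes went down: 35 of 61 fell and 5 rose (median -0.11, camera adjusted p = 0.00647, and adjusted p = 0.703 with an estimated correlation). RPL11 stood at -0.47, RPL7A at -0.45 and RPS25 at 0.42. Of 33 oxidative phosphorylation genes 19 fell and 5 rose (median -0.15, camera adjusted p = 0.0045, and adjusted p = 0.583 with an estimated correlation). SDHA stood at -0.77 and NDUFS1 at -0.46. Of 35 mitosis genes 21 fell and 7 rose (median -0.16, camera adjusted p = 0.00647, and adjusted p = 0.583 with an estimated correlation). AURKA stood at -1.06 and CDC20 at -0.60. Of 26 interferon-stimulated genes 12 fell and 3 rose (median -0.24, camera adjusted p = 0.0385, and adjusted p = 0.583 with an estimated correlation). IFIT1 stood at -1.34 and USP18 at -0.62.

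The other 23 lists did not pass camera after PRPF38A knockdown. Counts of members higher and lower were 7 and 3 of 11 B-complex genes, PRPF38A itself among those lower (camera adjusted p = 0.4), 8 and 4 of 18 U2 snRNP genes (0.104), 12 and 3 of 21 Prp19-complex genes (0.0829). They were 2 and 3 of 8 exon junction complex genes (0.83), 9 and 11 of 30 SR and hnRNP genes (0.891), 2 and 5 of 8 minor spliceosome genes (0.336) and 3 and 5 of 10 decay factors (0.681). They were 10 and 3 of 15 cohesion genes (camera adjusted p = 0.104), 10 and 18 of 34 replication genes (0.125), 3 and 7 of 22 recombination repair genes (0.4), 3 and 2 of 9 anti-apoptotic genes (0.83). Counts were 9 and 6 of 20 pro-apoptotic genes (0.528), 8 and 6 of 20 p53 targets (0.891), 13 and 4 of 23 stress response targets (0.0749) and 3 and 5 of 13 heat shock genes (0.732). They were 5 and 15 of 30 proteasome genes (camera adjusted p = 0.0938), 0 and 0 of 13 mitochondrially encoded mRNAs (0.538), 6 and 13 of 22 cholesterol genes (0.0938), 15 and 6 of 25 glycolysis and hypoxia genes (0.0938). Among cell markers they were 8 and 4 of 18 basal markers (0.104), 4 and 8 of 15 luminal markers (0.4), 3 and 2 of 10 mesenchymal markers (0.891) and 1 and 2 of 9 immune or endothelial markers (0.83). The median, the mean and the camera direction differed in sign for the B-complex, SR and hnRNP, anti-apoptotic and p53 target lists. Adjusted over the list alone, the counts were the same except for the SR and hnRNP genes (10 higher, 12 lower), mitosis genes (7 and 22), NF-kB genes (16 and 0), proteasome genes (5 and 16) and mesenchymal markers (2 and 2).

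The interferon call of PRPF38A knockdown ended without PRPF38A knockdown replicate 5 (camera adjusted p = 0.0501), with only the compared groups (0.0687) and at a mean CPM of at least 5 (0.178). At that mean CPM the U5 list (0.0986) and the transcripts degraded by nonsense-mediated decay (0.0563) also missed the threshold, and the histone list, with fewer than 3 members left, was not tested. Lists passed that otherwise did not: the Prp19 and stress response lists without PRPF8 knockdown replicate 3 (0.0497 each), both higher, and, both lower, the proteasome list without control replicate 1 (0.0402) or 3 (0.0425) and the cholesterol list without control replicate 4 (0.0404). In the authors' deposited table, 11041 genes had an adjusted p under 0.05, 5141 higher and 5900 lower, and the 10509 genes called there and in the edgeR fit had the same sign in both.

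**Figure D2:**
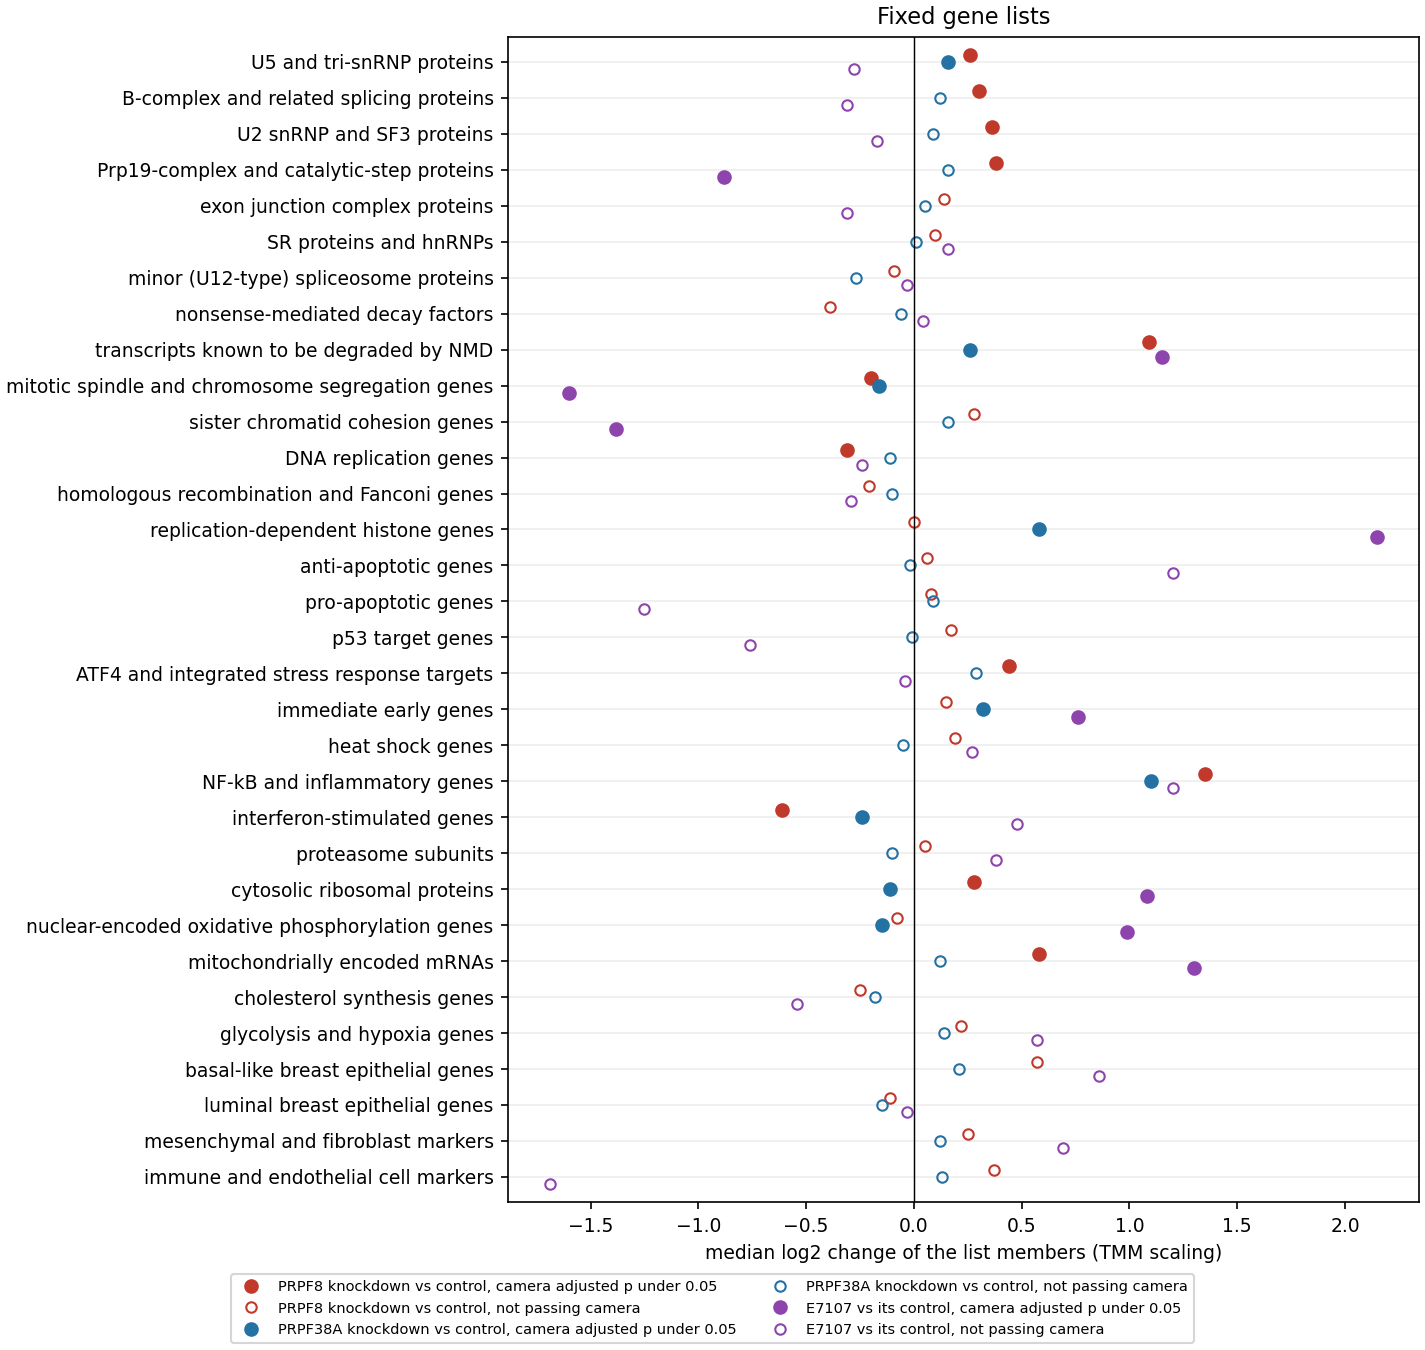
Median log2 change (TMM scaling) of the measured members of each of the 32 fixed lists, for each knockdown and E7107 against control. Circles are filled where camera's adjusted p was under 0.05 at the preset correlation and open elsewhere, and open circles carry no call. NF-kB genes lie at 1.35 and 1.10 in the knockdowns and mitosis genes at -1.60 with E7107. Of the filled circles, that of immediate early genes with E7107 (0.76) changes sign on the TPM scale, to -0.12.

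The knockdowns were also compared with each other, in the fit of all 3 groups. ACTG2 (log2 difference 4.00 ± 0.12, SE), the growth factor HBEGF (2.88 ± 0.08) and CTGF (2.80 ± 0.14) were higher with PRPF8 knockdown than with PRPF38A knockdown, and C17orf58 (-2.74 ± 0.07), the lysyl oxidase LOXL2 (-2.71 ± 0.10) and the transcription factor FOS (-2.70 ± 0.39) were lower. PRPF38A differed by 4.88 and PRPF8 by -4.09. The adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 3.59e-05, that of FOS. In all, 11736 of 19758 genes differed, 5897 higher and 5839 lower with PRPF8 knockdown, with 904 and 1420 at least 2-fold. With only the compared groups in the fit, 11608 of 18590 differed. On the log2(TPM + 0.1) scale the median of all genes was -0.20, and the calls split into 3535 higher and 8616 lower.

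Between the knockdowns, ribosomal protein genes had the smallest camera adjusted p and transcripts degraded by nonsense-mediated decay the largest median difference. Of 61 ribosomal protein genes, 56 were higher with PRPF8 than with PRPF38A knockdown and 1 was lower (median 0.40, camera adjusted p = 3.38e-15, and adjusted p = 0.418 with an estimated correlation). RPL11 and RPL34 stood at 0.81. Of 16 transcripts degraded by nonsense-mediated decay 13 were higher and 1 lower (median 0.87, camera adjusted p = 1.18e-06, and adjusted p = 0.418 with an estimated correlation). GADD45A stood at 1.71 and SNHG16 at 1.43. Higher and lower counts were 13 and 2 of 18 U2 snRNP genes (camera adjusted p = 0.00694, and adjusted p = 0.418 with an estimated correlation), 8 and 1 of 11 B-complex genes, PRPF38A included (0.0144, and adjusted p = 0.418 with an estimated correlation), and 14 and 3 of 21 Prp19-complex genes (0.0214, and adjusted p = 0.67 with an estimated correlation). The B-complex list holds PRPF38A, whose difference the design sets; without it 7 of 10 genes were higher and 1 lower, and the mean went from 0.59 to 0.17 (camera adjusted p = 0.044). SF3B4 differed by 0.65, SF3B1 by 0.64, PRPF4B by 0.49, SMU1 by 0.38, RBM22 by 0.97 and PLRG1 by -1.41. Of 8 exon junction complex genes 5 were higher and none lower (camera adjusted p = 0.0372, and adjusted p = 0.418 with an estimated correlation). MAGOH stood at 0.87 and RNPS1 at 0.50. Of 30 proteasome genes 19 were higher and 4 lower, with PSMD6 at 0.58 and a median of 0.15 that turned to -0.06 on the TPM scale (camera adjusted p = 0.0372, and adjusted p = 0.923 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 12 were higher and none lower (median 0.51, camera adjusted p = 0.0372, and adjusted p = 0.923 with an estimated correlation). MT-CO3 stood at 0.61. Replication genes were lower in 20 and higher in 5 of 34 (median -0.25, camera adjusted p = 0.0144, and adjusted p = 0.418 with an estimated correlation). POLD1 stood at -1.51 and MCM7 at -0.74. Histone genes were lower in 9 and higher in 1 of 14 (median -0.73, camera adjusted p = 0.0285, and adjusted p = 0.51 with an estimated correlation). HIST1H2AC stood at -2.09 and HIST1H2BD at -1.17. Relative to the median of all genes on the TPM scale, proteasome genes stood at 0.14, ribosomal protein genes at 0.40 and replication genes at -0.25.

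The other 22 lists did not pass camera between the knockdowns, with adjusted p from 0.0724 for oxidative phosphorylation to 0.963. The median, the mean and the camera direction differed in sign for the U5, decay factor, anti-apoptotic and pro-apoptotic lists. Adjusted over the list alone, 57 ribosomal protein genes were higher and 1 lower, 14 and 2 U2 snRNP genes, 6 and 0 exon junction complex genes, 20 and 4 proteasome genes and 13 and 0 mitochondrially encoded mRNAs; the other lists that passed kept their counts. At a mean CPM of at least 5, the camera adjusted p was 0.117 for the B-complex list, 0.0675 for the U2 snRNP list, 0.16 for the Prp19 list, 0.212 for the exon junction list, 0.254 for the proteasome list and 0.175 for the mitochondrially encoded list, and the histone list, with fewer than 3 members left, was not tested. The mitochondrially encoded call ended without PRPF8 knockdown replicate 3 (0.0678) or PRPF38A knockdown replicates 1 (0.0662), 2 (0.0726) or 4 (0.0501) and with only the compared groups (0.0509), the proteasome call without PRPF38A knockdown replicates 2 (0.0534) or 4 (0.0501) or with upper quartile scaling (0.0708), and the exon junction call without PRPF38A knockdown replicate 4 (0.0501) or with upper quartile scaling (0.0517). The oxidative phosphorylation list passed, higher with PRPF8 knockdown, without control replicate 5 (0.0422) or PRPF8 knockdown replicate 4 (0.0447).

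Changes of the knockdowns overlapped. Both knockdowns raised 4018 genes and lowered 4175, where independent lists would share 1860 and 2010, and 1102 genes were called in opposite directions. At a change of at least 2-fold, 697 genes were higher and 650 lower in both and 4 were opposite. Across genes, which are not independent replicates, the Pearson correlation of the log2 changes was 0.708 with a covariance of 0.468. The controls are shared: simulated unchanged groups against them gave a mean correlation of 0.042 and a covariance of 0.00176. These groups were drawn around the means of the same controls. The error of the controls therefore drops out, and the simulation cannot show what shared controls add. With the controls split into separate sets of 2 and 3 libraries, the correlation was 0.563 to 0.635 and the covariance 0.414 to 0.474. Neither step addresses siRNA transfection, since the titles call the controls untreated while the protocol names a non-targeting siRNA. If the controls were untreated, effects of transfection would be part of both knockdown changes and could not be separated here.

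PRPF8 knockdown raised retained introns and lowered the inclusion of cassette exons. Of 2781 retained-intron events tested, 429 had a higher share with the intron and 52 a lower share, and of 18195 skipped-exon events 391 had higher and 2474 lower inclusion. An intron of chromosome 7 (minus strand, 73151722 to 73151891, GRCh37 per the submitters' processing notes) went from a PSI of 0.08 ± 0.01 to 0.81 ± 0.051 (SD, n = 5 each; adjusted p = 8.2e-10 in limma), and 1 of chromosome 8 (plus strand, 145725583 to 145725649) from 0.138 ± 0.022 to 0.838 ± 0.075. Inclusion of an exon of chromosome X (minus strand, 153357642 to 153357765) went from 0.958 ± 0.025 to 0.278 ± 0.033, and that of an exon of chromosome 1 (plus strand, 32542765 to 32542919) from 0.858 ± 0.054 to 0.182 ± 0.058. The other classes went both ways, with 223 higher and 194 lower of 4877 alternative 3' sites, 281 and 110 of 3096 alternative 5' sites and 258 and 220 of 3075 mutually exclusive exons. In total 4632 of 32024 events were called in limma with Benjamini-Hochberg adjustment.

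PRPF38A knockdown moved events in the same directions in smaller number. Of 3271 retained-intron events 167 were higher and 21 lower, and of 20478 skipped exons 269 had higher and 1237 lower inclusion. Of the remaining classes, 129 and 95 of 5728 alternative 3' sites, 124 and 65 of 3560 alternative 5' sites and 158 and 102 of 3426 mutually exclusive exons were higher and lower, and 2367 of 36463 events were called in all. An intron of chromosome 19 (plus strand, 1274440 to 1274647) went from a PSI of 0.18 ± 0.021 to 0.648 ± 0.048 (SD, n = 5 each; adjusted p = 1.57e-06 in limma). An exon of chromosome 17 (plus strand, 5329556 to 5329619) went from 0.746 ± 0.034 in the controls to 0.174 ± 0.041 with PRPF38A knockdown, and an exon of chromosome 9 (plus strand, 37857238 to 37857348) from 0.742 ± 0.043 to 0.19 ± 0.039. Tested against each other, the knockdowns differed at 2192 of 32203 events. Retained introns were higher with PRPF8 knockdown in 268 and lower in 34, and exon inclusion was higher in 190 and lower in 1122. Both knockdowns raised 543 events and lowered 1134, where independent lists would share 36 and 125, and 15 were opposite. Across events the correlation of the PSI differences was 0.751 (covariance 0.00401), against 0.096 (2.95e-05) for simulated unchanged groups and 0.68 (0.0038) with split controls. Only the split controls are read here as bearing on the shared controls. The limit on transfection effects given for the genes holds for these events too.

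**Figure D3:**
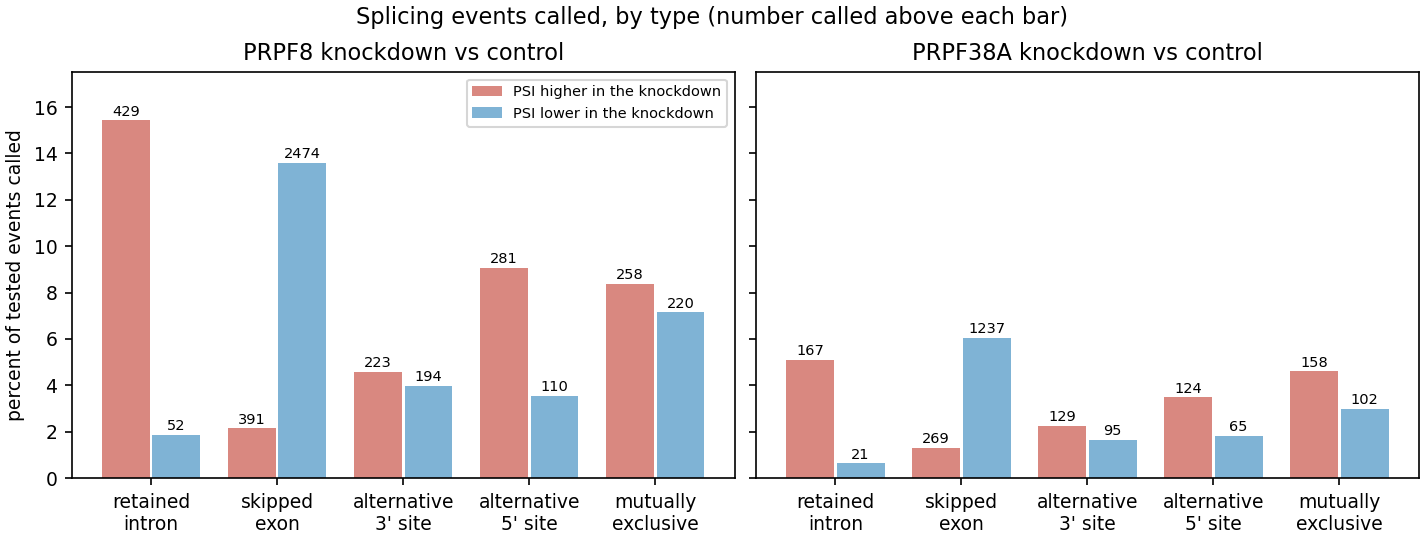
Percent of tested splicing events called with a higher or lower PSI in each knockdown against control, by event class, with the number of called events above each bar. Retained introns were called higher in 429 events with PRPF8 and 167 with PRPF38A knockdown, and skipped exons lower in 2474 and 1237.

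Transcripts annotated as retained intron took a larger share of TPM in all 3 treatments. The share was 3.451% ± 0.061 in the controls, 3.857% ± 0.089 with PRPF8 knockdown and 3.602% ± 0.037 with PRPF38A knockdown (SD, n = 5 each; exact permutation p = 0.0079 for each knockdown, the smallest possible, and 0.0253 adjusted over 16 tests), and all 5 libraries of each knockdown lay above all controls. With E7107 the share was 6.797% ± 0.236 against 3.439% ± 0.066 (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible, and 0.0508 after adjustment, which misses the threshold), again with every treated library above every control. The share of protein-coding transcripts was 76.409% ± 0.267 in the controls, 72.563% ± 0.894 with PRPF8 knockdown and 74.182% ± 1.002 with PRPF38A knockdown (SD, n = 5 each; exact permutation p = 0.0079, adjusted 0.0253). With E7107 it was 63.485% ± 1.471 against 79.034% ± 0.233 (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0508). Transcripts annotated as targets of nonsense-mediated decay held 3.552% ± 0.185 in the controls, 3.557% ± 0.115 with PRPF8 knockdown and 3.685% ± 0.064 with PRPF38A knockdown (SD, n = 5 each; exact permutation p = 0.944 and 0.159). With E7107 they held 2.974% ± 0.075 against 3.237% ± 0.036, with every treated library below every control (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0508, which misses the threshold). Transcripts annotated as processed transcript held 4.049% ± 0.056 in the controls, 4.056% ± 0.072 and 4.004% ± 0.046 in the PRPF8 and PRPF38A knockdowns (SD, n = 5 each; exact permutation p = 0.833 and 0.198). With E7107 they held 6.081% ± 0.178 against 4.138% ± 0.062 (SD, n = 4 each; exact permutation p = 0.0286, adjusted 0.0508). TPM has a fixed total per library, and these 4 biotypes leave out other and unannotated transcripts. With E7107 the protein-coding share fell by more than the retained-intron and processed-transcript shares rose together. A lower share is therefore not by itself a lower amount, nor a shift into retained-intron transcripts.

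Gene by gene, the share of retained-intron transcripts within a gene's TPM rose in 546 and fell in 47 of 4570 genes with PRPF8 knockdown, rose in 153 and fell in 22 with PRPF38A knockdown, and rose in 1634 and fell in 110 of 4484 genes with E7107 (limma with Benjamini-Hochberg adjustment). It was higher with PRPF8 than with PRPF38A knockdown in 300 genes and lower in 22. With PRPF8 knockdown the share went from 27.4% ± 12.6 to 95.6% ± 4.5 for the lipid kinase PI4KA and from 12.7% ± 2.1 to 58.7% ± 4.4 for the mitotic spindle gene CKAP2L (SD, n = 5 each), and for CKAP2L it was 61.8% ± 10.6 with PRPF38A knockdown. With E7107 it went from 1.5% ± 0.5 to 99.8% ± 0.1 for the splicing regulator SFSWAP and from 3% ± 1.1 to 98.5% ± 0.1 for DDI2 (SD, n = 4 each). In the authors' deposited table of transcripts, retained-intron transcripts with a q-value under 0.05 were higher in 2361 of 3550 cases (66.5%) for PRPF8, 1160 of 1569 (73.9%) for PRPF38A and 4331 of 5636 (76.8%) for E7107. Protein-coding transcripts in the authors' deposited table were higher in 42.4%, 43.8% and 29.6% of those past the same q-value.

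**Figure D4:**
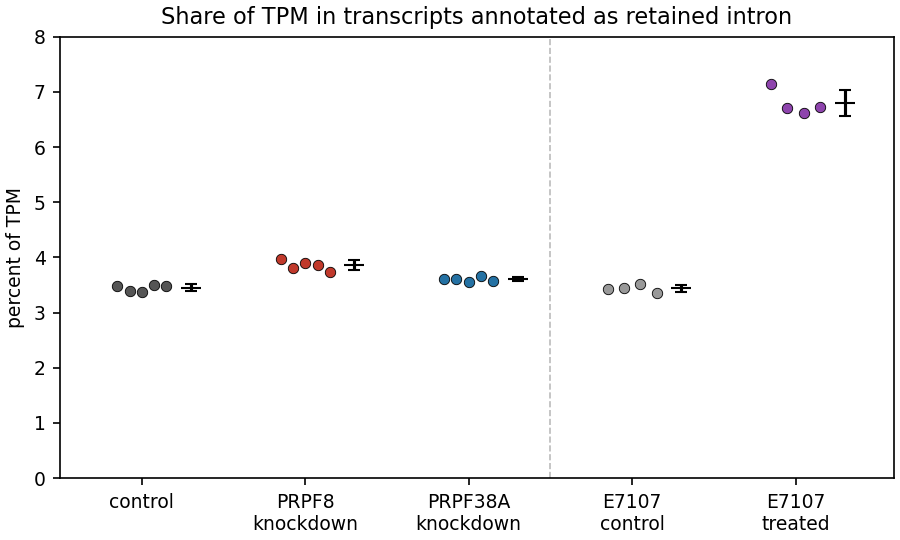
Percent of TPM in transcripts annotated as retained intron, with a point per library and a bar for the mean ± SD of each group (n = 5 per group, and n = 4 in the E7107 dataset right of the dashed line). Means are 3.451% in the controls, 3.857% and 3.602% in the knockdowns, and 3.439% and 6.797% in the E7107 controls and treated libraries.

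E7107 changed most of the transcriptome. The vesicle protein gene SFT2D3 had 0 counts in all 4 controls and 2349 to 3719 counts with E7107, at least 1780-fold higher against a floor of 3 counts per library. The cancer-testis antigen MAGEA4 (log2 change 8.41 ± 0.20, SE), the Wnt ligand WNT7A (8.04 ± 0.22) and the zinc finger gene ZFP30 (6.88 ± 0.10, from 8.819 to 1038 CPM) rose. ZNF469 (-7.33 ± 0.25), the sphingosine 1-phosphate receptor S1PR3 (-6.34 ± 0.16), the pro-apoptotic gene BIK (-6.11 ± 0.31) and the transcriptional coactivator ZMIZ1 (-6.00 ± 0.17) fell. The adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 5.88e-09, that of BIK. PHF5A (ENSG00000100410), a subunit of the SF3b complex, rose by 1.83 and PRPF38A fell by 1.97. SF3B1 (ENSG00000115524), the largest SF3b subunit, was 0.64 higher with TMM scaling but stood at -0.25 on the TPM scale. PRPF8 stood at -0.09 (adjusted p = 0.123 in edgeR's quasi-likelihood test), at -0.97 on the log2(TPM + 0.1) scale and at 0.18 with upper quartile scaling, and in the authors' deposited table at -0.38. In all, 15129 of 19069 genes were called, 7508 higher and 7621 lower, of which 5094 and 5178 changed at least 2-fold. On the log2(TPM + 0.1) scale the median of all genes was -0.82 and the calls split into 4235 higher and 11697 lower, and with upper quartile scaling the median was 0.27 and 8701 were higher and 6479 lower.

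Ribosomal protein, mitochondrial, histone and immediate early genes rose as groups with E7107. Of 61 ribosomal protein genes 59 rose and none fell (median 1.08, which is 1.02 above the median of all genes on the TPM scale; camera adjusted p = 3.16e-13, and adjusted p = 0.5 with an estimated correlation). RPL30 stood at 1.78 and RPS12 at 1.74. Of 33 oxidative phosphorylation genes 29 rose and 4 fell (median 0.99, or 0.92 relative to all genes on the TPM scale; camera adjusted p = 4.7e-05, and adjusted p = 0.5 with an estimated correlation). UQCRQ stood at 2.34 and NDUFV2 at -3.02. All 13 mitochondrially encoded mRNAs rose (median 1.30, camera adjusted p = 0.00134, and adjusted p = 0.626 with an estimated correlation), MT-ND3 by 1.78, and the mitochondrial share of counts was 4.16% to 5.94% against 2.12% to 2.3%. Of 15 histone genes 11 rose and 1 fell (median 2.15, camera adjusted p = 0.00537, and adjusted p = 0.342 with an estimated correlation). HIST1H1C stood at 3.92 and HIST2H2BE at 3.08. The histone and mitochondrially encoded genes have no introns, and protein-coding genes without introns had a median of 1.56 as a class. Camera compares a list with all genes, so it does not set these lists apart from that class. Of 16 transcripts degraded by nonsense-mediated decay 11 rose and 3 fell (median 1.15, camera adjusted p = 0.0073, and adjusted p = 0.342 with an estimated correlation). GADD45A stood at 3.47 and ZFAS1 at 2.00. Of 24 immediate early genes 16 rose and 4 fell, with a median of 0.76 that was -0.12 on the TPM scale, 0.70 above the median of all genes there (camera adjusted p = 0.00764, and adjusted p = 0.493 with an estimated correlation), and with JUN at 3.55 and DUSP1 at 3.03.

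Genes of chromosome segregation fell with E7107. Of 35 mitosis genes 27 fell and 7 rose (median -1.60, camera adjusted p = 0.000902, and adjusted p = 0.124 with an estimated correlation). The kinase AURKA stood at -3.44, the kinesin KIF11 at -3.15 and BIRC5 at 1.83. Of 15 cohesion genes 12 fell and 1 rose (median -1.38, camera adjusted p = 0.0073, and adjusted p = 0.342 with an estimated correlation). The cohesin subunit genes RAD21 and SMC3 stood at -2.04 and -1.97. Of 21 Prp19-complex genes 15 fell and 5 rose (median -0.88, camera adjusted p = 0.0468, and adjusted p = 0.558 with an estimated correlation). PLRG1 stood at -1.05 and DHX38 at 1.78. Relative to the median of all genes on the TPM scale, the list medians were -1.66 for mitosis, -1.42 for cohesion and -0.95 for Prp19-complex genes, 1.22 for mitochondrially encoded mRNAs, 2.06 for histones and 1.08 for transcripts degraded by nonsense-mediated decay.

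The other 23 lists did not pass camera with E7107. Most of their members were called singly, but so were 79.3% of all tested genes. Counts of members higher and lower were 5 and 9 of 16 U5 and tri-snRNP genes (camera adjusted p = 0.372), 4 and 7 of 11 B-complex genes (0.513), 6 and 9 of 18 U2 snRNP genes (0.595). They were 4 and 4 of 8 exon junction complex genes (0.894), 15 and 11 of 30 SR and hnRNP genes (0.41), 3 and 1 of 8 minor spliceosome genes (0.788) and 3 and 4 of 10 decay factors (0.877). They were 8 and 20 of 34 replication genes (camera adjusted p = 0.0821), 6 and 11 of 22 recombination repair genes (0.501), 5 and 3 of 9 anti-apoptotic genes (0.501), 5 and 14 of 20 pro-apoptotic genes (0.063). Counts were 3 and 13 of 20 p53 targets (0.0677), 10 and 11 of 23 stress response targets (0.881), 6 and 6 of 13 heat shock genes (0.745), 9 and 7 of 18 NF-kB genes (0.31) and 14 and 8 of 28 interferon-stimulated genes (0.186). They were 19 and 6 of 30 proteasome genes (camera adjusted p = 0.0835), 5 and 15 of 22 cholesterol genes (0.071), 17 and 7 of 25 glycolysis and hypoxia genes (0.0898). Among cell markers they were 11 and 7 of 18 basal markers (0.178), 5 and 6 of 15 luminal markers (0.573), 4 and 1 of 9 mesenchymal markers (0.342) and 0 and 7 of 8 immune or endothelial markers (0.16). The median, the mean and the camera direction differed in sign for the minor spliceosome and decay factor lists. Adjusted over the list alone, the counts were the same except for the immediate early genes (17 higher, 4 lower), the proteasome genes (20 and 6) and the mesenchymal markers (3 and 1).

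The Prp19 call with E7107 ended without E7107 treated replicate 1 (camera adjusted p = 0.0539), 2 (0.0521) or 3 (0.058) and with the replicate number as a block (0.0566). It also ended at a mean CPM of at least 5 (0.181), where the cohesion (0.0593) and histone (0.203) calls ended too. The proteasome list passed, higher, at that mean CPM (0.0135) and with upper quartile scaling (0.0121). With 1 library left out, 4 lists passed, all lower. The pro-apoptotic list did so without E7107 control replicate 1 (0.0462), 2 (0.0377), 3 (0.0403) or 4 (0.0488) or treated replicate 4 (0.0499). Without control replicate 1, 2 or 3 the p53 target list (0.0463, 0.0443 and 0.0403), the replication list (0.048, 0.0468 and 0.0464) and the cholesterol list (0.048, 0.0443 and 0.0403) did so too. In the authors' deposited table, adjusted p was under 0.05 for 17942 genes, 8206 higher and 9736 lower; of 14085 genes called there and in the edgeR fit, 14003 had the same sign, and its log2 changes lay a median of -0.294 from those of the edgeR fit.

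The E7107 changes were compared with the knockdown changes gene by gene. The autophagy gene GABARAPL1 rose by 3.62 with PRPF8 knockdown, 1.94 with PRPF38A knockdown and 1.62 with E7107, the transcription factor CEBPD by 1.84, 1.5 and 4.85, and the kinase DYRK2 by 2.08, 1.42 and 3.95. SFXN2 stood at -3.75, -2.12 and -1.94, the phosphoglucomutase-like gene PGM2L1 at -1.70, -1.62 and -4.15, UNC119B at -2.10, -1.67 and -1.37, and the replication-fork repair gene TONSL at -2.98, -1.59 and -1.26, all called. Of 18000 genes tested in both datasets, 1603 were higher in all 3 comparisons and 2107 lower. Both knockdowns, which share controls, raised 3837 and lowered 4059 of these genes, and E7107 calls independent of them would give 1418 and 1706. PRPF8 knockdown and E7107, whose controls are separate, both raised 2751 genes and both lowered 3378 (2403 and 2825 for independent lists), with 4606 opposite and a correlation across genes of 0.198. PRPF38A knockdown and E7107 both raised 2022 and both lowered 2768 (1887 and 2308 for independent lists), with 3980 opposite and a correlation of 0.132. At a mean CPM of at least 5, PRPF38A knockdown and E7107 both raised 1552 and both lowered 1877 genes, where independent lists would share 1526 and 1817, and the correlation was 0.059. For PRPF8 knockdown and E7107 these counts were 2003 and 2224, against 1817 and 2090, and the correlation was 0.134. The change itself differed between E7107 and PRPF8 knockdown for 15963 of 21566 genes and between E7107 and PRPF38A knockdown for 15743, by edgeR's quasi-likelihood contrast with Benjamini-Hochberg adjustment.

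Protein-coding genes were also grouped by intron number, a grouping added after seeing the data. With E7107 the median log2 change was 1.56 for 248 genes without introns, 0.32 for 1106 genes with 1 to 2 introns, 0.02 with 3 to 5, -0.33 with 6 to 10, and -0.51 both with 11 to 20 and with over 20; on the TPM scale the medians ran from 0.62 for genes without introns to -1.30 for those with over 20 and were below 0 in all classes with introns. Among genes without introns 73.0% were higher and 17.7% lower, and among those with over 20 introns 22.5% and 55.3%. With PRPF8 knockdown the medians ran from 0.15 for 252 genes without introns, -0.08 on the TPM scale, to -0.18 for 1769 genes with over 20 introns, and with PRPF38A knockdown from 0.24 to -0.08. At a mean CPM of at least 10, the median of genes without introns less that of genes with over 10 introns went from 0.28 to 0.19 with PRPF8 knockdown, from 0.31 to 0.15 with PRPF38A knockdown and from 2.07 to 2.42 with E7107. In each library, the median log2 CPM of genes without introns less that of genes with over 10 introns was 0.258 ± 0.078 with E7107 and -1.937 ± 0.054 in its controls (SD, n = 4 each; exact permutation p = 0.0286, also after adjustment over the 3 comparisons). It was -1.835 ± 0.043 with PRPF8 knockdown, -1.951 ± 0.023 with PRPF38A knockdown and -2.364 ± 0.091 in the controls (SD, n = 5 each; exact permutation p = 0.0079, adjusted 0.0119). All treated libraries of each comparison lay above all their controls. Within 4 classes of exonic length, from the shortest to the longest, the median log2 change of genes without introns less that of the other genes was 0.53, 0.10, 0.00 and -0.18 with PRPF8 knockdown, so this contrast was gone or turned among the longer genes. It was 0.45, 0.27, 0.19 and 0.03 with PRPF38A knockdown, over 132, 59, 41 and 20 genes without introns in both, and 1.37, 1.02, 2.5 and 2.29 with E7107, over 131, 60, 40 and 17. Over all genes of a class the trend with intron number remained, though weakly in the longest class with E7107. The Spearman correlation of the change with exon number was -0.196, -0.194, -0.178 and -0.161 with PRPF8 knockdown. It was -0.21, -0.149, -0.115 and -0.115 with PRPF38A knockdown, and -0.141, -0.106, -0.098 and -0.041 with E7107.

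**Figure D5:**
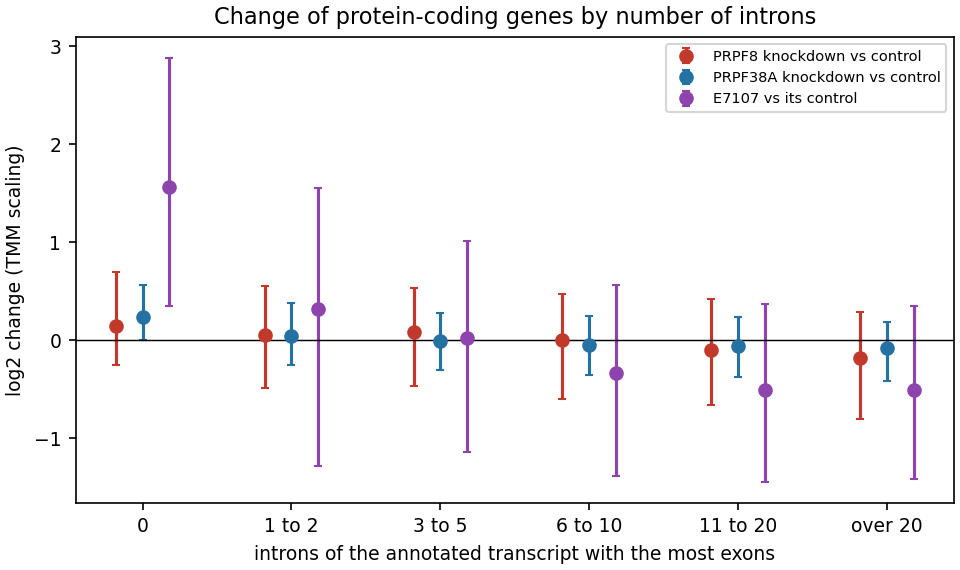
Median log2 change (points, TMM scaling) and quartiles (bars) of protein-coding genes, grouped by the number of introns of the annotated transcript with the most exons, in each comparison. With E7107 the median goes from 1.56 for genes without introns to -0.51 for those with over 20, and on the TPM scale the medians are 0.62 and -1.30.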

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

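The tests of explanations and the counts of other splits below were written down after the results had been seen. Of 312 groups of libraries examined, 24 had a library far from the rest of its group, while chance gives about 1 in 20 groups, or about 16. PRPF8 knockdown replicate 3 accounts for 10 of them, among 113 genes examined.

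PRPF8, the core protein of the U5 snRNP, stood at 405 CPM in control replicate 5 against 259 to 269 in the other 4 controls. Higher expression of the whole gene goes against the full-length transcript, which had 54.7 TPM there and 55.5 to 67.5 in the other controls, and RNA of a PRPF38A knockdown goes against 175.8 CPM of PRPF38A there (others 164.8 to 179.8). The excess could lie over the 3' end of the gene. The 3 transcripts with the largest excess, of 16 annotated, were short ones of chromosome 17 (minus strand, 1650629 to 1653911, GRCh38). They held 122% of the gene's excess TPM, at 40.8 TPM against 0.6 to 4.6 in the other controls. Being chosen by this excess, they would hold a large share of it in any case, but the choice did not set their position. What produced such a local excess was not tested, and the design gives no biological explanation to test. Without this library the log2 change of PRPF8 with PRPF38A knockdown was 0.54 (adjusted p = 9.17e-06 in edgeR's quasi-likelihood test) in place of 0.40.

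PRPF8 knockdown replicate 3 stood apart from the other 4 libraries of its group in 1116 of 9482 genes, 757 higher and 359 lower, while the other libraries of the group had 24 to 60 such genes and control replicate 5 had 405. A weaker knockdown or control RNA goes against the slope of its changes on those of the other libraries, 1.004 (others 0.965 to 1.018), and lower depth against the 50 genes apart in the library of nearest depth. Mitochondrial RNA alone goes against the 1101 genes apart without mitochondrially encoded genes, and a length bias against a Spearman correlation of its deviations with exonic length of 0.115 across genes, inside the range of the other libraries (-0.155 to 0.162). No biological explanation was tested, and the cause stays open. KLF15, a transcription factor chosen after its values were seen, had 4530 CPM in this library, against 135 to 548 in the other 4 libraries of its group and 276 to 912 in the controls. Other values far from the group were a mitochondrial share of 4.41% (others 2.74% to 3.14%), MT-ND1 at 1861 CPM (979 to 1122), PRPF4B at 293 (242 to 251), DDX46 at 288 (262 to 268), ZFAS1 at 633 (596 to 605), HIST1H2AC at 5.9 (4.58 to 4.89), ICAM1 at 525 (618 to 634), IGFBP5 at 677 (788 to 815), PPP1R15A at 101 (117 to 121) and ACTG2 at 11.8 (15.1 to 15.6).

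With E7107, genes without introns were higher and genes with many introns lower. The scaling of the libraries moves both classes alike and cannot give their difference of 2.07 in median log2 change, and low counts go against the 2.42 that remained at a mean CPM of at least 10. For genes without introns, transcript length goes against the smallest difference within 4 classes of length, 1.02 (the class of the longest transcripts, with 17 genes without introns, had 2.29). For genes with many introns, length is not settled. The Spearman correlation of the change with exon number was -0.162 over all genes. Within the classes, from the shortest to the longest, it was -0.141, -0.106, -0.098 and -0.041. The pattern may come from a loss of mature RNA of genes with introns while intronless genes kept their amount, but the intronless median was 0.62 on the TPM scale and these data hold no outside standard, so a loss and a gain cannot be told apart.

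Other values far from their group were, among the controls, PRPF4B at 96.8 CPM in replicate 5 (others 111 to 114), RPL5 at 1090 in replicate 4 (1169 to 1196), MX1 at 36.9 (32.2 to 33.3) and IFIT1 at 8.07 (6.66 to 6.97) in replicate 3, and CLK3 at 20.9 in replicate 2 (23 to 23.9). PRPF38A knockdown replicate 2 had RPL7A at 1009 CPM (1040 to 1042), RND3 at 192 (178 to 182) and C17orf58 at 12.2 (10.8 to 11.2). In the E7107 dataset, control replicate 1 had S1PR3 at 38.9 CPM (36.6 to 36.9) and JUN at 69 (72.2 to 72.7), control replicate 3 had BCL2L1 at 114 (121 to 123), control replicate 4 had HIST1H1C at 3.53 (3.77 to 3.8), and treated replicate 1 had NDUFV2 at 21.6 (25.8 to 26.6).

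Changes differed between E7107 and PRPF8 knockdown in 15963 genes and between E7107 and PRPF38A knockdown in 15743, by edgeR's quasi-likelihood contrast. In 30 of 8820 splits of the libraries for each, only 1, the real split, gave as many, and the highest other split gave 14526 and 15037. Mixing the groups takes away the changes themselves, so the splits address only the case that nothing changed in either dataset. They do not test whether the changes differ. The high splits were the 2 of each draw that kept the E7107 groups, and the 27 mixing them gave at most 3889 and 1138, which points to the structure of the samples: most of these counts rests on the E7107 changes.

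Splits were also counted for the single comparisons. They treat the libraries as independent units, which the labels do not establish, so they cannot exclude a difference of culture or batch between groups. Mixing groups that differ also widens the spread within a split, which holds down its count. Of 60 of the 126 splits, none but the real split gave as many genes for PRPF8 knockdown (13910, highest other 2033), PRPF38A knockdown (10993, highest other 1) and their difference (11736, highest other 1), nor as many splicing events (4632, 2367 and 2192, highest others 1, 1 and 4). All 35 splits of the E7107 dataset were counted, with 15129 genes and 1744 retained-intron shares for the real split and 0 and 0 for the highest other. For retained-intron shares in the knockdown dataset 100 splits gave at most 4, 0 and 1, against 593 for PRPF8, 175 for PRPF38A and 322 for their difference.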

How the results depend on the processing

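Unless stated, alternatives were fixed before the data were examined; the retained-intron shares per gene and the classes by intron number were chosen after seeing the data. With 1 library left out at a time, called genes were 13559 to 14102 for PRPF8 knockdown, 10376 to 11513 for PRPF38A knockdown, 11276 to 11933 between the knockdowns and 14874 to 15400 for E7107. The E7107 difference in retained-intron share was 3.242 to 3.416 percentage points, with an exact permutation p of 0.0571 each, the smallest that 3 against 4 libraries can give. At a mean CPM of at least 5, where fewer genes are tested, 9205 genes were called for PRPF8, 9621 for E7107, and 9696 and 9631 for the differences of E7107 from the PRPF8 and PRPF38A changes, and calls of at least 2-fold numbered 1921 (PRPF8), 522 (PRPF38A), 879 (between knockdowns) and 5374 (E7107). On the log2(TPM + 1) scale, where the pseudocount shrinks low genes, 2439, 558 and 1017 genes reached 2-fold for PRPF8, PRPF38A and between knockdowns. At a PSI difference of at least 0.2, 1855, 691 and 634 events were called (retained introns 238, 56 and 118, skipped exons 1181, 457 and 394), and with at least 50 reads 3050 events and 292 retained introns for PRPF8 and 190 retained introns between knockdowns, from fewer events tested.

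At least 2-fold, 697 genes were higher and 650 lower in both knockdowns (99 and 123 for independent lists, 4 opposite), 625 and 855 with PRPF8 knockdown and E7107 (404 and 703 for independent lists, 657 opposite), and 290 and 258 with PRPF38A knockdown and E7107 (187 and 222 for independent lists, 312 opposite). The correlation of the knockdowns was 0.56 with no filter and 0.66 with DESeq2. For PRPF8 and E7107 it was 0.175 with no filter, 0.134 at a mean CPM of at least 5 (2224 genes lower in both) and 0.217 with DESeq2, and for PRPF38A and E7107 0.059 at that mean CPM and 0.16 with DESeq2. On the TPM scales, PRPF8 and E7107 shared 1071 (TPM + 1) and 1077 (TPM + 0.1) higher and 6488 and 6490 lower genes, and PRPF38A and E7107 1056 and 1039 higher and 4388 and 4295 lower; that scale lowers the median of all genes with E7107. SF3B1 with E7107 reversed from 0.64 to -0.25 on both TPM scales (adjusted p = 0.000218 and 0.000205 in limma). Counts over TPM were 1 factor per gene and 1 per library, to within 0.181% in the E7107 files, so the TPM scale moves genes alike: PRPF8 went from -0.09 to -0.97 and the median of all genes from 0.002 to -0.82 on the log2(TPM + 0.1) scale. The reversal is this common shift.

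With PRPF8 and PRPF38A left out of the lists, chosen after seeing the data, no list changed its call in the knockdown comparisons. No list passed camera with an estimated correlation in any comparison (0 of 32), while fry, which does not compare a list with other genes, called 28 for PRPF8, 26 for PRPF38A, 24 between knockdowns and 31 for E7107. At a mean CPM of at least 5 camera called 7, 5 and 3 lists for PRPF8, PRPF38A and between knockdowns. With 1 library left out, it called 10 to 13, 8 to 11, 7 to 11 and 8 to 13 lists. With the replicate number as a block, 13849, 11010, 11766 and 14719 genes were called, and the Prp19 list with E7107 had an adjusted p of 0.0566; no other list changed its call. The numbers do not pair the samples: correlations of same-numbered libraries ran from -0.07 to 0.11, and 2, 1 and 1 of 5 and 1 of 4 libraries correlated best with their own number. Among the named genes, calls and directions held except for SF3B1 with E7107 on the TPM scales, PRPF38A with PRPF8 knockdown (not called on the TPM scales, 0.06, adjusted p = 0.376 and 0.322) and PRPF8 with E7107, called lower or higher under 7 alternatives, from -0.97 to 0.18. With PRPF8 knockdown the median of all genes was -0.21 on the log2(TPM + 0.1) scale, so PRPF38A moved with the common shift of that scale. Depth limits which events were tested, with 32024 for PRPF8 at 20 informative reads, 37094 at 10 and 23595 at 50; its effect on the calls was not simulated.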

Other observations

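Members of lists that did not pass camera with E7107 changed singly, in both directions, in edgeR's quasi-likelihood test, which called 79.3% of all tested genes. Of 9 anti-apoptotic genes 5 rose and 3 fell (camera adjusted p = 0.501), with MCL1 at a log2 change of 2.46, BCL2L1 at 1.20 and XIAP, an inhibitor of apoptosis, at -1.98. Of 20 pro-apoptotic genes 5 rose and 14 fell (camera adjusted p = 0.063), with the pore-forming BAK1 at -3.05. Of 28 interferon-stimulated and interferon genes 14 rose and 8 fell (camera adjusted p = 0.186), with IFNB1 at 7.38 and IFIT2 at 3.91. Of 18 NF-kB genes 9 rose and 7 fell (camera adjusted p = 0.31), with the cytokine IL6 at 4.46 and the inhibitor TNFAIP3 at 4.06. Of 23 stress response targets 10 rose and 11 fell (camera adjusted p = 0.881), with XBP1, a transcription factor of the unfolded protein response, at -4.96. Of 30 SR and hnRNP genes 15 rose and 11 fell (camera adjusted p = 0.41), with the splicing kinase CLK1 at 3.10 and the SR protein SRSF2 at 2.22.

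Lists that did not pass in the knockdowns also held single genes that rose, with others that fell. Of all tested genes, 70.4% were called with PRPF8 knockdown and 55.6% with PRPF38A knockdown. Of 25 glycolysis and hypoxia genes 13 rose and 9 fell with PRPF8 knockdown (camera adjusted p = 0.569, log2 changes from -1.48 to 1.85) and 15 rose and 6 fell with PRPF38A knockdown (0.0938, from -0.89 to 1.06), with the glycolytic enzyme ENO1 at 1.02 and 1.06. Of 8 exon junction complex genes 5 rose and 1 fell with PRPF8 knockdown (camera adjusted p = 0.116, from -0.15) and 2 rose and 3 fell with PRPF38A knockdown (from -0.23), with RNPS1 at 1.55 and 1.05. With PRPF8 knockdown, 11 of 18 basal markers rose and 4 fell (camera adjusted p = 0.07, from -2.06), with the keratin KRT17 highest at 2.15, and 16 of 30 SR and hnRNP genes rose and 7 fell (0.298, from -0.94), with the splicing kinase CLK3 highest at 1.32.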
